A study of Mus musculus with 2 samples.

How the data were processed

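Gene expression was measured on Affymetrix arrays in dorsal skin of female NC/Nga mice, an inbred strain prone to dermatitis, after dermatitis had been induced with house dust mite ointment. Per the labels' protocols, the mice entered at 6 weeks of age, mite ointment and ZAG were each given for 6 weeks, and skin was taken at 13 weeks. RNA was prepared with a column kit, and sense cDNA was fragmented and end-labelled with biotin, per the labels' protocols. The series design text names 3 mice in each group and a ZAG dose of 1 µg/mL. The table used here holds 1 column per group, labelled control and ZAG, so 2 arrays in all. Whether a column is the RNA of 1 mouse, a pool of mice or a mean of arrays is not given in the sources used here.

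The deposited values are on a log2 scale, which was inferred from the numbers. They range from 0.889 to 12.75 in the control column and from 0.866 to 13.19 in the ZAG column, and read as natural or decimal logarithms the upper values would exceed what an array scanner records. The background correction, summarisation, normalization and software behind these log2 values are not given in the sources used here. The medians of the deposited columns were 3.33 and 3.36. The sorted columns differed by 0.0159 on average and by 0.437 at most, so they had a common scale but were not quantile normalized at the level of the table. No detection calls were used here. Array number limits the precision: with 1 array per group no replicate error, standard error or p-value can be given, and each difference describes these 2 arrays.

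The table has 33793 probes. The platform annotation gave 1 gene symbol for 23521 probes, several for 1814 and none for 8458. The gene identifiers of 23328 single-symbol probes were found in a reference gene table (assembly GRCm38.p6), with 0 symbols differing. No coordinates are given because the build behind the array annotation is not named in the sources used here. Probes with 1 symbol were used, and the 1082 genes with more than 1 probe were averaged, which gave 22180 genes. The log2 difference of each gene was taken as ZAG minus control on the values as deposited. Genes with a difference of at least 1 in size (2-fold) were counted among the 11090 genes whose mean level over both arrays was at or above the median of all genes (3.87).

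Gene lists, 38 in number, were fixed before the data were examined. For each of the 36 lists with at least 5 measured genes, the median difference was set against 10000 random lists of the same size, drawn within 20 bins of mean level from genes outside the list. A list was called low below percentile 2.5 and high above percentile 97.5. About 1.8 of the 36 lists tested would fall outside by chance if genes varied independently. Genes of one pathway or cell type vary together between any 2 skin samples, so more lists than that would fall outside between 2 arrays of 1 group. The percentile therefore describes the 2 arrays and does not test the treatment. The red blood cell list had 2 measured genes and the mitochondrially encoded list had 0, and neither was tested. As a gauge of background, added after the data were seen, the 95th percentile of the mean levels of 1394 olfactory and vomeronasal receptor genes was taken (3.16). A gene below it on 1 array is given as "at least" a fold, with the gauge as the floor. A gene below it on both arrays is given no fold. The numbers of 2-fold genes given for the lists use the same floor.

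The genes named were chosen by a rule fixed before the data were examined. It took 20 genes set by the study's subject and the 10 genes with the largest positive and the 10 with the largest negative difference at or above the median level, with at most 3 of a family and without predicted genes and small or variable families. It also took up to 2 genes each way from every list. Other genes are named as members of a list, and those were chosen after their values were seen.

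The procedure was tested on simulated data that kept the real mean levels, shuffled the differences within bins and added known shifts. Among 200 simulated lists of 25 genes out of 22180, 5% were called with no shift and 97.5% with a shift of 0.25. The rate with no shift follows from the percentile limits. Shuffling breaks the way genes of one pathway or cell type vary together, so neither rate carries over to the real lists. For the 2-fold counts, 200 genes among 11090 were shifted. A true shift of 1 passed in 54% of genes, 1.5 in 96%, 2 in 99.5% and 3 in 100%. Alternatives were median centring, quantile normalization and loess of the difference on level (span 0.3), the brightest probe per gene, other filters on level, a 1.5-fold threshold, unmatched random lists, list means, and members above the gauge or in no other list. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9 were used. Probes with several or no gene symbols were left out of the comparison.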

Results

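Skin transcript levels were compared between NC/Nga mice with mite-induced dermatitis that received recombinant ZAG and mice with the same dermatitis that did not. ZAG is zinc-alpha-2-glycoprotein, a secreted protein encoded by Azgp1 and known for mobilising lipid from fat. The comparison asks how gene expression in inflamed skin differs with topical ZAG. Each group had 1 array, so no value below carries a replicate error and no difference was tested against one. Over all 33793 probes, log2 values of the 2 arrays correlated across probes with Pearson's r = 0.988, where probes are not independent replicates. The SD of the log2 difference was 0.317 and its median was 0.02. Among 591 genes at or above the median level with more than 1 probe, the SD between probes of the same gene was 0.244, which gives a scale for probe error but not for differences between mice.

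Far more genes were lower than higher in the ZAG-treated skin. Of 11090 genes at or above the median level, 128 (1.15%) were at least 2-fold lower and 30 (0.271%) at least 2-fold higher. At least 4-fold differences were seen for 21 lower genes and 1 higher gene. Among genes with 1 symbol at or above that level, Il1b, the gene of the inflammatory cytokine interleukin-1 beta, differed most, with a log2 difference of -3.59 (8.84 in control and 5.25 with ZAG). It was followed by Saa3, an acute-phase serum amyloid gene (7.80-fold lower), and Csta3, a cysteine protease inhibitor of the stefin family (6.65-fold lower). Spink7, a serine protease inhibitor gene, was 6.27-fold lower, the collagenase gene Mmp13 6.21-fold, the cornified envelope precursor gene Sprr1b 5.74-fold and the protease gene Tmprss11b 5.53-fold. Il19, a cytokine gene of the IL-10 family, was at least 4.33-fold lower, Clec4e, a pattern recognition receptor gene of myeloid cells, at least 4.08-fold, and Trem1, a myeloid activating receptor gene, at least 4.96-fold, since all of them were below the background gauge in the ZAG array.

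**Figure D1:**
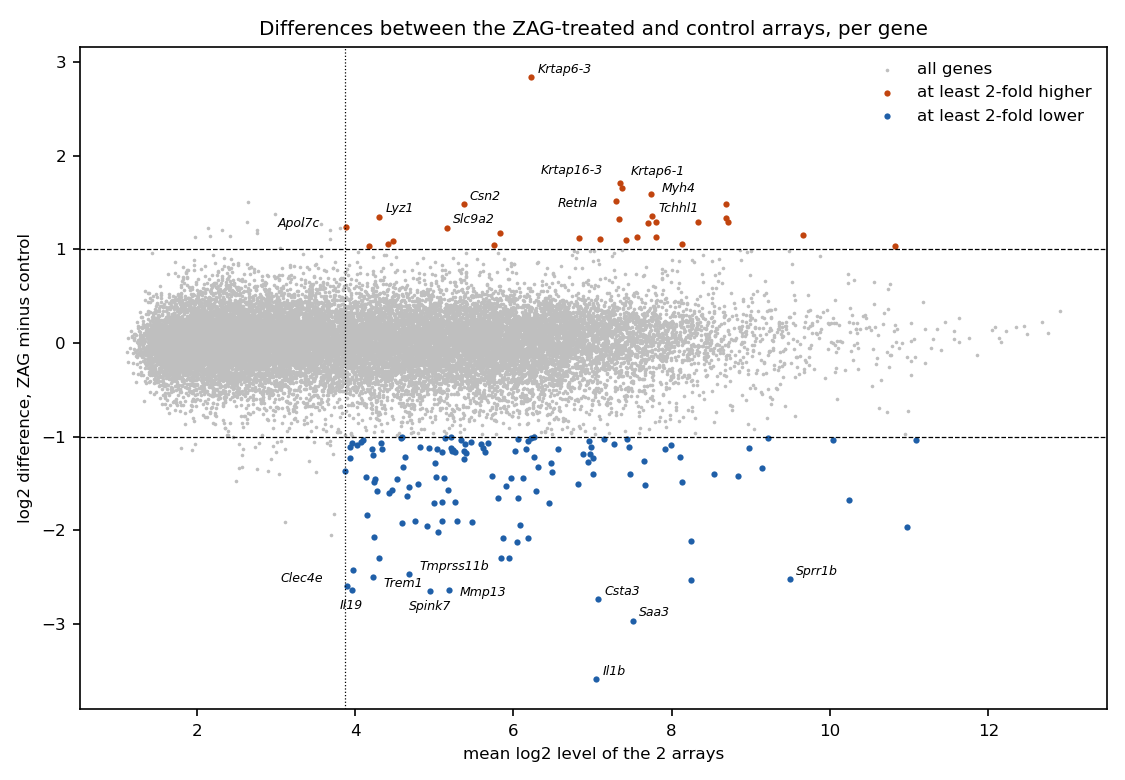
Log2 difference (ZAG minus control) against the mean log2 level of the 2 arrays, 1 point per gene (22180 genes). Dashed lines mark 2-fold and the dotted line the median level of 3.87; 128 genes lie below the lower line and 30 above the upper one at or above that level, with the genes of the largest differences named.

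The genes higher in ZAG-treated skin were led by hair genes. Krtap6-3, a keratin-associated protein gene of the hair shaft, was 2.84 higher on the log2 scale, Krtap16-3 was 1.71 higher and Krtap6-1 was 1.66 higher. Of the 30 genes, 13 were hair keratin-associated protein genes and 2 were of the skeletal muscle list. The fast muscle myosin gene Myh4 was 1.59 higher. Retnla, a resistin-like gene induced in type 2 responses, was 1.52 higher, the milk protein gene Csn2 was 1.49 higher, the trichohyalin-like gene Tchhl1 1.36 and the lysozyme gene Lyz1 1.35. Apol7c was 1.24 higher, and Slc9a2, a sodium-proton exchanger gene, 1.23.

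Azgp1 itself was dim. Its log2 level was 2.55 in control and 3.26 with ZAG, the former below and the latter just above the background gauge of 3.16, so the difference is at least 1.07-fold. The arrays read the mouse transcript and not the applied protein.

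Among the epidermal lists, read here in dorsal skin, genes of activated keratinocytes were lower with ZAG while the main filaggrin and loricrin genes differed little. The keratinocyte activation list had a median log2 difference of -0.86 over 24 measured genes, below all 10000 random lists. Of these, 19 genes were lower and 11 were at least 2-fold lower. Besides Sprr1b, the keratin genes Krt6b and Krt16, which mark wounded and inflamed epidermis, had log2 differences of -1.97 and -1.67. S100a8 and S100a9, genes of the calprotectin subunits made by stressed keratinocytes and neutrophils, were 2.63-fold and 2.80-fold lower. Members in the other direction included S100a7a (0.98) and Slurp1 (0.34), while Krt17 (-0.08) and Sprr1a (0.00) hardly differed. Without the 5 members that stand in another list as well, among them S100a8, S100a9 and the matrix gene Tnc, the median was -0.30, still below all random lists.

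The cornified envelope and late differentiation list had a smaller median of -0.18 over 39 genes (-0.29 after loess), also below all random lists, with 26 lower and 2 at least 2-fold lower. These were Lce3d (2.51-fold lower) and Rptn (2.05-fold lower). Flg, which encodes the barrier protein filaggrin, differed by -0.18 and Lor, which encodes loricrin, by -0.21, each less than the SD of 0.244 between probes of one gene. Ivl, the gene of the envelope protein involucrin, was 0.65 higher and Lce1m 0.48 higher. Basal keratinocyte genes had a median of -0.48 over 11 genes, with 10 lower, among them the hemidesmosome integrin gene Itgb4 (-0.87) and the laminin gene Lama3 (-0.75). The stem cell keratin gene Krt15 was 0.66 higher. Barrier lipid and ceramide genes (30 genes, median -0.04, percentile 11.7) and junction genes (16 genes, median 0.15, percentile 93.6) lay within the range of random lists. In the former list the lipoxygenase gene Alox12b had a difference of -0.72, and in the latter the tight junction gene Ocln had 0.76 and the plakoglobin gene Jup -0.72.

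Innate inflammatory genes were lower as a group. The list of innate inflammatory cytokines had a median of -0.67 over 23 genes, below all random lists. It held 18 lower genes, of which 6 were at least 2-fold lower with the gauge as the floor. After Il1b, the chemokine gene Ccl3 was at least 4.05-fold lower. Ptgs2, the inducible cyclooxygenase gene, had a log2 difference of -1.91, while Ccl5 (0.38) and Il18 (0.20) were among the 5 members in the other direction. Immediate early and heat shock genes, a list fixed as a sign of tissue handling, were also lower, beside this list and the keratinocyte activation list. Their median was -0.17 (percentile 0.73) and their mean -0.29 (percentile 0.02), with Nr4a1 at -1.70 and Fos at -1.51. Over the 22 at or above the median level their median was -0.11, within the random range (percentile 4.75). In this list 14 genes were lower and 9 higher, the latter including the chaperone genes Hsph1 (0.43) and Dnajb1 (0.30). The type 17 and 22 list had a median of -0.27 over 25 genes (percentile 0.01), with 7 genes at least 2-fold lower. The median was -0.44 over its 15 members at or above the median level, and the list mean was -0.49. Besides Il19, these included the cytokine gene Il24 (at least 2.94-fold lower, below the gauge with ZAG), the neutrophil chemokine gene Cxcl5 (-1.60) and the antimicrobial peptide gene Defb3 (-1.44). Of the lymphocyte cytokines that name this list, Il17a (2.71 and 3.04) and Il22 (1.52 and 1.26) were below the gauge on both arrays, so no direction is given, and Il17f was 0.64 higher.

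Type 2 inflammation genes as a list did not stand apart, with a median of -0.06 over 26 genes (percentile 10.7). Of these, 12 had mean levels below the gauge, so the list median partly reads background. Individual members differed by more than 2-fold. Il33, the gene of an epithelial alarmin, was 3.26-fold lower, and Il4ra, the gene of the receptor chain shared by IL-4 and IL-13, was 2.27-fold lower, whereas Retnla was 2.87-fold higher. Tslp, Il4, Il31, Ccl17 and the interferon gene Ifng were below the gauge on both arrays, so no fold is given. Il13 (log2 3.49 and 3.37) and Ccl22 (3.91 and 3.85) were little above it. Ccl11, the gene of the eosinophil attractant eotaxin, was 1.23-fold lower. The interferon response list had a median of -0.10 over 27 genes (percentile 4.80), with log2 differences of -0.85 in Oasl2 and -0.80 in Usp18. Over its 18 members at or above the median level the median was -0.16 (percentile 2.23). The itch and neuroinflammation receptor list also lay within the random range (17 genes, median -0.10, percentile 6.87), with 9 below the gauge. Its member Osmr, the gene of a receptor chain for oncostatin M and IL-31, was 2.17-fold lower.

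**Figure D2:**
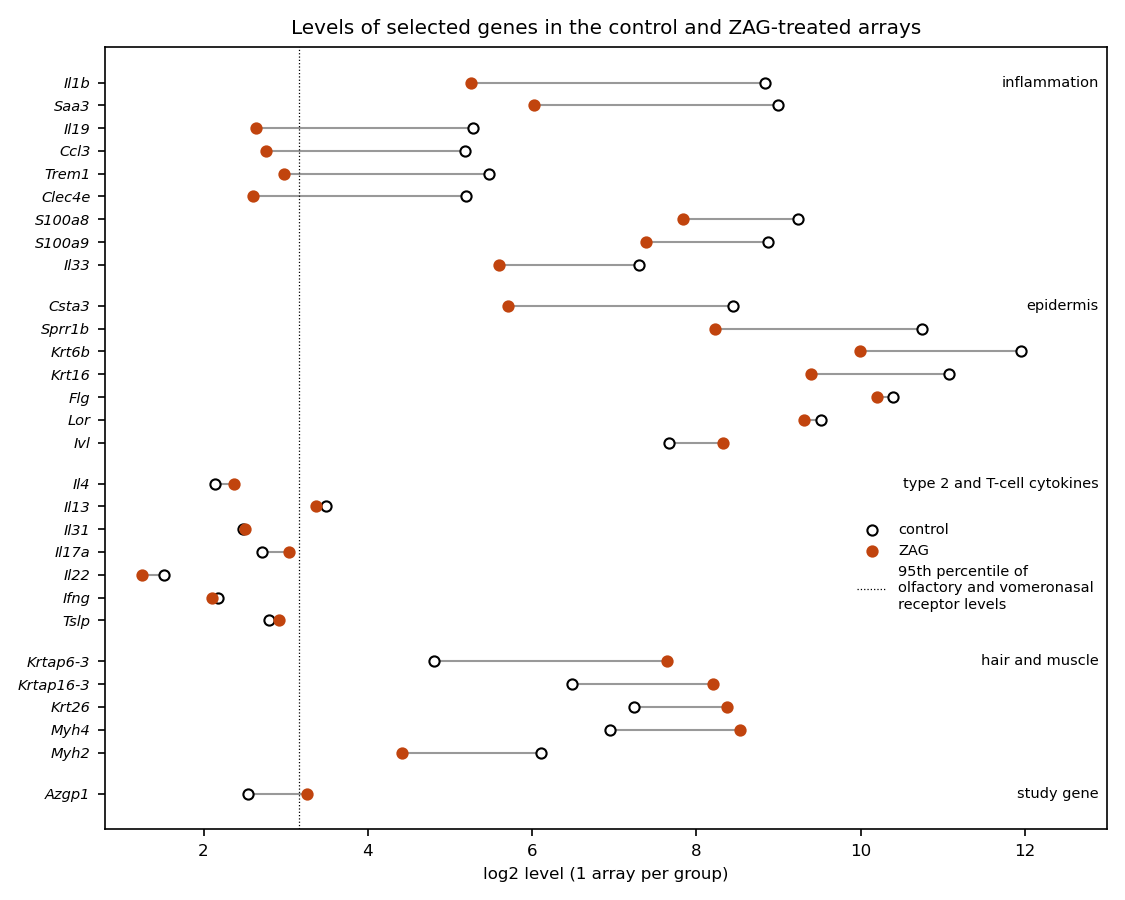
Log2 level of selected genes in the control array (open circles) and the ZAG array (filled circles), 1 array per group and without error bars. Inflammatory genes such as Il1b (8.84 and 5.25) are separated widely, while Flg (10.39 and 10.20) is not, and most type 2 and T-cell cytokines lie at or below the dotted line, the 95th percentile of olfactory and vomeronasal receptor levels (3.16).

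Adam17, the gene of a sheddase of cytokines and EGFR ligands, was 0.23 higher, within the SD between probes of one gene. The list of ADAM17, Notch and EGFR ligand genes had a median of -0.20 over 24 genes (percentile 0.09), with 18 lower. The largest differences were in genes of the EGFR ligands epigen (Epgn, 2.28-fold lower) and HB-EGF (Hbegf, 2.17-fold lower). Of the Notch receptor genes in the list, Notch1 differed by 0.07, Notch2 by -0.53 and Notch3 by -0.13. Fxyd5, the gene of a regulator of the sodium pump and of cell adhesion, had a log2 difference of -0.58.

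Markers of several immune and stromal cell types were lower in the ZAG array. The eosinophil and neutrophil list had a median of -0.32 over 26 genes, below all random lists, and -1.49 over its 11 members at or above the median level. Its 9 genes at least 2-fold lower with the gauge as the floor included Clec4e, Trem1, the gelatinase gene Mmp9 (-2.13) and the neutrophil chemokine receptor gene Cxcr2 (-1.05). In this list 14 genes had mean levels below the gauge, among them the eosinophil genes Epx, Prg2, Siglecf and Ccr3 and the neutrophil genes Ly6g, Ngp, Camp and Elane. Of this list, 7 genes stand in another list as well. Macrophage and monocyte genes had a median of -0.46 over 25 genes, with 20 lower. Cd14, the gene of the endotoxin co-receptor, had a log2 difference of -1.94 and the integrin gene Itgam was at 5.84 in control and 4.84 with ZAG, while Lyz1 was 1.35 higher and the chemokine receptor gene Ccr2 0.34 higher. Mast cell genes had a median of -0.56 over 14 genes. Hdc, the gene of the histamine-forming enzyme, was at least 4.90-fold lower, and the log2 difference was -0.95 in the tryptase gene Tpsb2 and -0.79 in the IgE receptor gene Fcer1a. Macrophage and mast cell medians were both below all random lists. The medians of the eosinophil and neutrophil list and of the macrophage list were thus lower beside those of the keratinocyte activation and innate cytokine lists.

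Fibroblast and matrix genes had a median of -0.59 over 31 genes, with 28 lower and 6 at least 2-fold lower, and endothelial genes a median of -0.43 over 21 genes, with 20 lower. Both were below all random lists. Besides Mmp13 and Mmp9, the matrix gene Tnc (-2.11) and the protease inhibitor gene Timp1 (-1.66) were lower, while the abundant dermal gene Dcn differed by 0.04. Selp and Sele, genes of the selectins that capture leukocytes on activated vessels, were 4.91-fold and 2.96-fold lower. T and NK cell genes did not stand apart over all 23 measured genes (median -0.10, percentile 4.67). Over the 8 at or above the median level the median was -0.33 (percentile 0.44). In this list Cd4 was 2.08-fold lower and Cd3g 0.72 higher on the log2 scale. Langerhans and dendritic cell genes (21 genes, median 0.05, percentile 64.1, but 0.22 and percentile 98.8 over the 13 at or above the median level) and B and plasma cell genes (15 genes, median 0.04, percentile 60.9, with 12 below the gauge) lay within the random range. Cd207, the gene of the Langerhans cell lectin langerin, was 0.53 higher. The basophil list lay within the random range too (7 genes, median -0.18, percentile 6.06, with 4 below the gauge).

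Hair, fat, sebaceous and muscle genes were higher in the ZAG array. Hair keratin-associated protein genes had a median of 0.75 over 51 genes, with 46 higher. Probes of near-identical copies were not told apart here, so single members of the Krtap, Sprr and Myh families are uncertain. Hair-shaft and inner root sheath genes had a median of 0.46 over 29 genes, with 28 higher, led by the inner root sheath keratin genes Krt26 (1.13) and Krt72 (0.98). Adipocyte genes had a median of 0.41 over 16 genes, with 15 higher, including the fatty acid binding protein gene Fabp4 (0.57) and the lipid droplet gene Plin1 (0.57). Sebaceous gland genes had a median of 0.33 over 17 genes, with the desaturase gene Scd3 at 0.75 and the fatty acid binding protein gene Fabp5 at -0.49. Skeletal muscle genes had a median of 0.35 over 34 genes, with 24 higher. In that list Myh4 and the calcium buffer gene Pvalb (1.12) were at least 2-fold higher, while Myh2 was 3.23-fold lower and Myh1 had a log2 difference of -0.92. The other lower members included the actinin gene Actn2 (-0.82) and the nebulin gene Neb (-0.17). All of these medians were above all 10000 random lists.

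Over all measured members, the lipid metabolism lists lay within the random range. Lipolysis and fatty acid oxidation genes had a median of 0.15 over 19 genes (percentile 93.5), with 16 higher, and of 0.22 over the 16 above the gauge (percentile 98.8). This list shares 3 genes with other lists, among them Lipe with adipocytes and Cidea with the sebaceous gland. The triglyceride lipase genes Pnpla2 (-0.15) and Lipe (-0.13) differed little, and the monoglyceride lipase gene Mgll was 0.49 higher. Fatty acid, triglyceride and sterol synthesis genes had a median of -0.06 over 21 genes (percentile 11.1), from -0.40 in Srebf2 to 0.45 in Insig1.

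**Figure D3:**
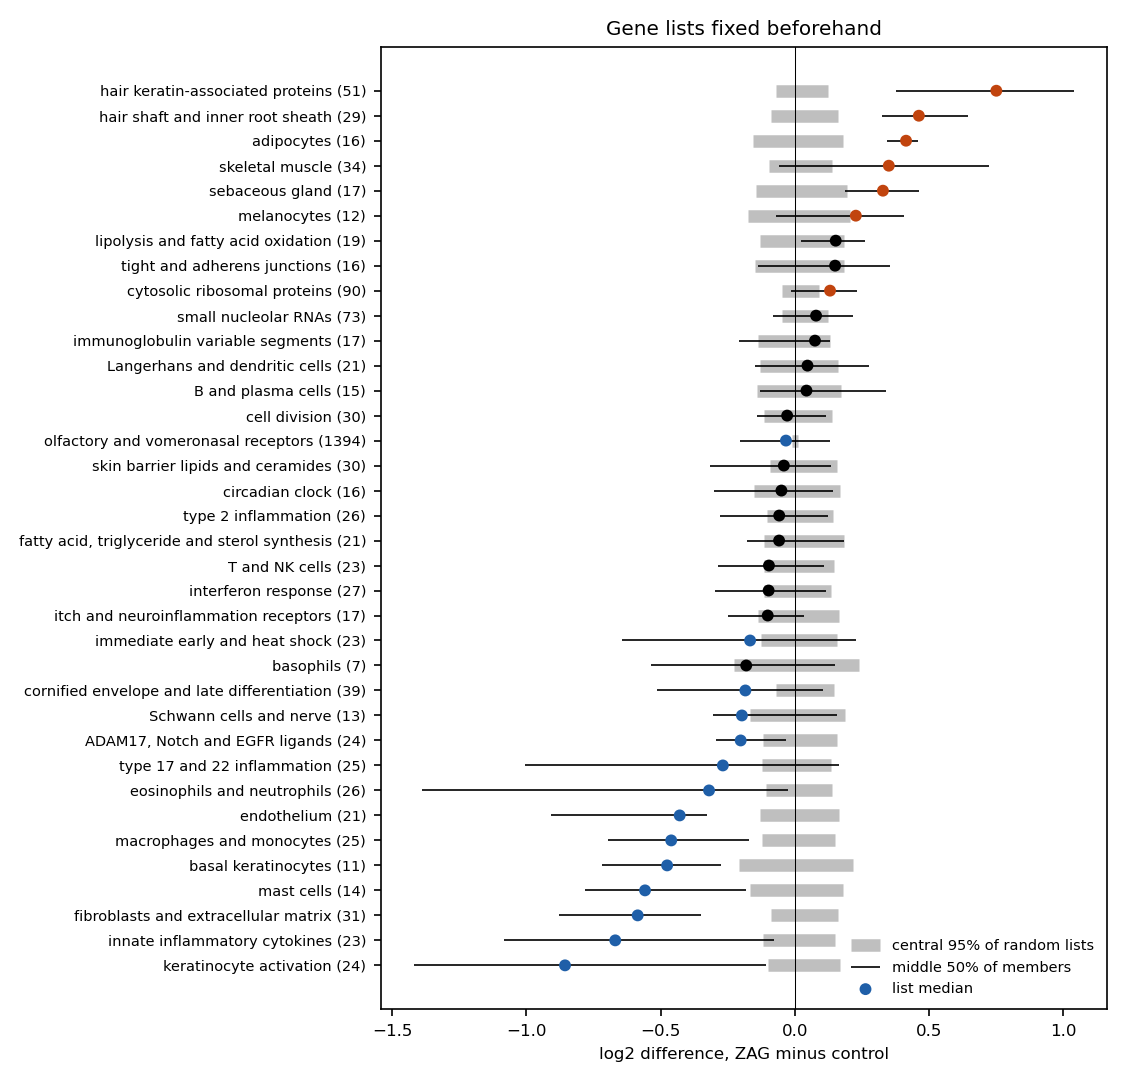
Median log2 difference (ZAG minus control) of 36 gene lists fixed beforehand, with the number of measured genes in brackets. Black lines span the middle 50% of members and grey bars the central 95% of 10000 random lists matched on level; 14 medians lie below the bars (blue), 7 above (red) and 15 inside (black), from -0.86 for keratinocyte activation to 0.75 for hair keratin-associated proteins.

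In all, 14 of the 36 lists tested were low, 7 were high and 15 lay within the central 95% of random lists. With 1 array per group, a difference caused by the treatment and one between the sampled pieces of skin are the same difference in these data.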

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

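Probes that the comparison leaves out also differed between the arrays. Among the 8458 probes with no gene symbol, 56 were at least 2-fold higher and 28 at least 2-fold lower in the ZAG array than in the control array, at any level. The highest of them, probe 17326936, was at 3.34 in control and 6.90 with ZAG (a log2 difference of 3.56), a larger difference in that direction than that of any gene with a symbol of its own. The lowest, probe 17457800, had a difference of -1.90. Among the 1814 probes with several gene symbols, 1 was at least 2-fold higher and 22 at least 2-fold lower. Their extremes were 1.01 and -2.38. The genes of these probes are not named here, and no explanation was tested for them.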

How the results depend on the processing

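Rescaling the arrays changed little. Under median centring, quantile normalization and loess, 128 to 138 genes were at least 2-fold lower and 29 to 30 at least 2-fold higher, and all 36 list calls held. The brightest probe per gene and unmatched random lists changed no list call either. The level filter and the threshold set the counts. Without a filter 46 genes were higher, at or above the 75th percentile of level 62 were lower, and at 1.5-fold 275 were higher and 563 lower, since these settings admit more or fewer genes by construction. Lower genes made up 81.0% of calls as deposited and 67.2% at 1.5-fold. Of the list calls, Schwann cells and nerve (median -0.20) was lost at or above the median level (-0.16), with list means (-0.14) and above the background gauge (-0.20). Immediate early and heat shock was lost at or above the median level (-0.11) and melanocytes with list means (0.17). The small negative median of olfactory and vomeronasal receptors turned to 0.012 at or above the median level and to 0.040 above the gauge. Inside the random range, the median of immunoglobulin variable segments turned from 0.07 to -0.21 above the gauge, and that of Langerhans and dendritic cells from 0.05 to -0.0041 after loess. In the other direction, the interferon, T and NK cell, Langerhans and dendritic cell, and lipolysis lists passed the threshold under at least 1 alternative filter or summary. The cause of these changes was not tested. The median of keratinocyte activation moved from -0.86 to -0.30 over members in no other list, a setting added, like the gauge, after the data were seen. No gene named by the rule lost its 2-fold difference under another scaling or probe choice. No paired analysis was possible because each group has 1 array, and leaving out an array leaves no comparison. Background correction could not be varied from the table of processed values. Genes near the gauge of 3.16, among them most lymphocyte cytokines, are limited by signal over background.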

Other observations

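The tests of dilution, of myeloid cells as the whole cause, of cross-hybridization, of growing follicles and of the muscle layer were chosen only after the results they bear on were seen. Cell division genes did not follow the keratinocyte activation genes. Their median was -0.03 over 30 genes (percentile 23.5), from -0.49 in Plk1, a mitotic kinase gene, to 0.42 in Tyms, the thymidylate synthase gene, and the proliferation marker gene Mki67 was at -0.37. Immediate early and heat shock genes had a median of -0.17 over 23 genes (percentile 0.73) and a mean of -0.29 (percentile 0.02). Over the 22 at or above the median level the median lay within the random range (-0.11, percentile 4.75). The list was divided. Nr4a1 (-1.70), Fos (-1.51) and Dusp1 (-1.23) were more than 2-fold lower, while the chaperone genes Hsph1 (0.43) and Dnajb1 (0.30) were higher. Other immediate early genes were lower too, such as Ier3 (-0.91), Zfp36 (-0.64) and Egr1 (-0.62), while Jun (0.22), Egr2 (0.27) and Atf3 (0.25) were higher. Whether tissue handling lowered these genes, or the inflammatory genes beside them, was not tested. Circadian clock genes lay within the random range (16 genes, median -0.05, percentile 22.9), with differences of -0.77 in Bhlhe40 and 0.31 in Dbp.

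Melanocyte genes had a median of 0.23 over 12 genes (percentile 98.6, within the random range when list means are used), with differences of 0.80 in Mlana and -0.49 in Kit, which mast cells also express. Schwann cell and nerve genes had a median of -0.20 over 13 genes (percentile 1.26, within the random range at or above the median level or with list means), with a difference of -0.75 in the adhesion gene Ncam1. The ribosomal protein list took every gene whose symbol starts with Rpl or Rps, so it can hold other genes and holds the paralogs Rpl7l1 (0.90) and Rpl3l (0.47). It was 0.13 higher at the median over 90 genes (percentile 99.9) and 0.08 after loess (percentile 99.5). Small nucleolar RNAs (73 genes, median 0.08, percentile 81.8) and immunoglobulin variable segments (17 genes, median 0.07, percentile 86.5) lay within the random range. Of the latter, 12 were below the gauge, and the median of the 5 above it was -0.21 (percentile 9.15). Olfactory and vomeronasal receptors, used as the background gauge, had a median of -0.03 over 1394 genes, below all random lists because the large list makes that range narrow (-0.01 to 0.01). Of the 10 highest genes, Csn2, Tchhl1, Apol7c and Slc9a2 stand in no list.

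Keratinocyte activation and innate inflammatory genes were lower together (47 genes, median -0.71), and the median after loess was -0.74, which argues against scaling that depends on level. Dilution of epidermal and immune RNA by follicle, muscle or fat tissue would lower other epidermal and immune lists alike. That holds only for genes which the added tissue does not make, and this was not checked. The median of 5 other epidermal and immune lists lay 0.646 above the pattern's (bootstrap 95% interval over members 0.135 to 1.04). That of 10 lists at or above the median level lay 0.836 above (0.209 to 1.02). The comparison left out the eosinophil and neutrophil (-0.32), macrophage (-0.46) and mast cell (-0.56) lists, which were also lower. The pattern's own lists had the lowest medians of the 36, so some gap was given beforehand. The lists compared were thus lower by less than the pattern. For the reasons given, the size of the gap does not decide on dilution as the whole cause. Dilution stays possible, since basal keratinocyte (-0.48) and type 17 and 22 genes (-0.27) were lower. Whether dilution lowered the fibroblast, endothelial, mast cell and macrophage lists is open: at or above the median level, T, NK, Langerhans and dendritic genes lay 0.656 above them (0.332 to 0.897), but T and NK genes were at -0.33 and Langerhans and dendritic genes at 0.22. All of these intervals resample genes within 1 pair of arrays. Such genes vary together and are not replicates, so the intervals do not measure differences between skin samples. Within the pattern, 12 epithelial keratin and Sprr genes had a median of -1.07, which direct loss of myeloid cell RNA would not give. These genes are members of the pattern itself and were chosen after it was seen. An indirect effect of fewer neutrophils and other myeloid cells on keratinocytes was not tested, so that cause stays open. A smaller infiltrate may account for part of the myeloid genes. An effect of ZAG and a difference between the animals or RNA samples behind the arrays cannot be told apart, because each group has 1 array.

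Hair keratin-associated protein genes were higher (51 genes, median 0.75). The median after loess was 0.70, which argues against level-dependent scaling. The hair-shaft and inner root sheath list, which holds none of these genes, was 0.46 higher, so hair genes outside this family were higher too. That value was known when the comparison was chosen. It cannot show how far cross-hybridization spread or enlarged the differences within the family, so this stays open. More growing follicles in the ZAG sample stay open: 6 follicle regulators and the melanocyte list had a median of 0.26 over 18 genes, but all of these belong to lists already seen to be higher, so this decides nothing. The cell division list, which a larger follicle matrix would raise if nothing else changed, was at -0.03. It reads the epidermis as well, where basal keratinocyte genes were at -0.48, so it decides nothing either. An effect of the treatment was not tested apart from the hair cycle at the sampled site.

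Skeletal muscle genes were higher (34 genes, median 0.35), and 0.31 after loess, so level-dependent scaling is argued against. The 10 brightest muscle genes were all higher, with a median of 0.74, but they are members of the list itself and so restate the pattern. More of the muscle layer in the ZAG sample stays open. The members did not all move together: 10 of the 34 genes were lower. Among them were Myh2 (-1.69) and Myh1 (-0.92), of a family whose single members are uncertain, and Actn2 (-0.82), outside that family. Others of the 10, such as Des (-0.12) and Ttn (-0.01), differed by less than the SD of 0.244 between probes of one gene. These values do not decide for or against more muscle.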
